A study of Mus musculus with 42 samples.

How the data were processed

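Small RNA was measured in 24 libraries (lysates and EVs of control or BDNF-treated cortical neurons, 6 libraries in each of 4 groups) and 18 gene libraries were made from hippocampal neurons (control and BDNF, 6 each, control EV and BDNF EV, 3 each), 42 samples in all. Per the labels' protocols, neurons were plated in medium with horse serum that was then exchanged for maintenance medium with B27 supplement, RNA was isolated with miRNeasy or RNeasy kits, small RNA libraries were made with the NEBNext kit from 150 ng of RNA and gene libraries with the TruSeq RNA kit v2 from 500 ng, and both were run on a HiSeq2000, the gene libraries with single reads of 50 bp. The kit for genes does not mark strand, per its usual description, so genes on opposite strands at 1 place cannot be told apart. Both tables hold raw counts per miRNA or gene as deposited by the authors, not normalised. Per the submitters' processing notes, CASAVA 1.8.2 and 1.8, cutadapt 1.8.1 and DESeq2 (with no version) were used with the mm10 build; the aligner, the counter and the annotation release are not given in the sources used here.

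The RNA table held 55471 Ensembl gene entries, 19513 of them at 0 in every library; 55144 had a symbol in the reference annotation (GRCm38.p6, the assembly of mm10), and the 327 without one held 0.0247% of the counts. The small RNA table held 1915 mature miRNA entries, 542 of them at 0 in every library. In 13 sets of entries with identical counts, which name 1 mature miRNA under several precursors, the 16 duplicates were counted once. No table column was left without a sample. Coordinates are those of the reference annotation in GRCm38.p6, counted from 1, and none was found for Gm45774.

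Groups, batches and replicate numbers were taken from the labels, which do not say what a batch is. Small RNA numbers 1 to 3 belong to batch x and the others to batch z. Hippocampal set 1 is batch a, sets 2 and 3 batch b, sets 4 and 5 batch c and set 6 batch d. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) with TMM normalisation, edgeR's expression filter with a minimum count of 10, the batch as a covariate and Benjamini-Hochberg adjusted p under 0.05. The hippocampal comparisons used all 18 libraries, EV against lysate and the difference of effects all 24 small RNA libraries, and BDNF against control the lysates alone or the EVs alone. Folds carry standard errors or 95% intervals from the fit. Group levels are CPM with TMM factors, for miRNAs over all 24 libraries.

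Named genes followed a fixed rule. Among calls with a mean of at least 2 CPM (20 CPM for miRNAs), the 10 highest and the 10 lowest log2 fold changes were taken, plus the 2 called members of each list with the largest change. Where fewer than 10 passed, all were taken, plus the 3 smallest unadjusted p values in each direction. The 5 most abundant miRNAs and miR-132-5p, miR-132-3p, miR-218-5p and miR-690 were always given; these last are linked with the study and are not independent evidence. Predicted genes, clone-named genes and pseudogenes were skipped where a named gene followed. Other list members given as examples, and miRNAs such as miR-451a, miR-124-3p and let-7i-5p where the rule does not reach them, were chosen after their values were seen.

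The 23 gene lists were immediate early genes, late activity and BDNF response genes, ERK pathway feedback targets, cholesterol biosynthesis, excitatory synapse and postsynaptic density, presynaptic vesicle cycle, dendrite growth and cytoskeleton, astrocyte, microglia and macrophage, oligodendrocyte lineage, vascular and fibroblast, inhibitory neuron and excitatory neuron markers, progenitor and proliferation genes, interferon response, NF-kB and inflammatory genes, unfolded protein and integrated stress response, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cytosolic ribosomal proteins, extracellular vesicle biogenesis and erythrocyte genes. The 9 miRNA lists were neuron-enriched, activity and BDNF regulated, Dlk1-Dio3 cluster, let-7, miR-17-92 clusters, blood and immune, liver and serum, glial with vascular and mesenchymal, and the miR-29 and miR-30 families. Lists with at least 3 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list by itself, on balance 1 way or in either direction. Camera p values were adjusted over the lists of a comparison. The groups, tests, covariates, lists, naming rule and the first set of alternatives were fixed before the data were examined.

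Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means, without removing the batch. It was over 0.1 in every pair for BDNF against control in EVs (0.286 to 0.724), in lysates (0.463 to 0.670) and in hippocampal neurons (0.349 to 0.577), for control EV (0.295 to 0.446) and BDNF EV (0.297 to 0.438) against control and for BDNF EV against control EV (0.185 to 0.564), so these numbers were taken to pair the samples. Within batches it was −0.122 to 0.103 in EVs, −0.0350 to 0.391 in lysates and −0.0619 to 0.0346 in hippocampal neurons, and −0.0682, 0.0776 and −0.0219 for the EV-treated groups, so the pairing rests mainly on the shared batch. No library was a duplicate of another: the lowest chi-square per degree of freedom between libraries of a group was 2.49.

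The procedure was tested on counts simulated from the real means and library sizes, with a seeded set of changed genes. At a 1.5-fold and a 2-fold change it recovered 88.5% and 96.3% for BDNF in lysates (498 miRNAs), 14.8% and 66.7% for the difference of effects (496 miRNAs), 86.6% and 94.0% for BDNF in hippocampal neurons (17398 genes), 77.6% and 91.0% for control EV (17403 genes) and 77.6% and 94.0% for BDNF EV against control (17395 genes). EV libraries were the shallowest, with 579 to 847 (control) and 536 to 804 (BDNF) miRNAs detected, against 818 to 923 and 887 to 950 in lysates, so rare miRNAs are measured least precisely there. Intervals cover the fitted spread, and PCR copies cannot be told from molecules since no molecular identifiers are named.

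Alternatives tried were size factors by relative log expression, DESeq2 1.42.0, no filter, a minimum count of 50, the replicate number as a block in place of the batch, no batch term, an adjusted p under 0.1, only the groups compared in the fit or all small RNA libraries in it, miR-9-5p left out, each library left out in turn, and camera against fry. Chosen after the data were seen were single batches, the libraries of highest Gm42418 left out, the shallowest EV libraries (control EV 8 and BDNF EV 8) left out, lysate counts thinned to EV totals, an axis of spread within groups as a covariate, and controls split between comparisons. For the overlap of control EV and BDNF EV calls, unchanged groups were simulated against the shared controls (10 simulations). Reads, protein, EV particle data and any samples other than these 42 were not analysed here, and a few genes that the naming rule reached are not reported here.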

Results

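Primary cortical neurons from NMRI mouse embryos of day 16 were given brain-derived neurotrophic factor (BDNF, 50 ng/ml for 20 min) or vehicle after about a week in culture. Small extracellular vesicles (EV) from the medium and lysates of the same kind of culture were collected 16 h later for small RNA sequencing, with 6 libraries each of control EV, BDNF EV, control lysate and BDNF lysate. In a further experiment hippocampal neurons were left as controls (n = 6), given BDNF (n = 6), or exposed for 24 h to EVs from control donors (n = 3) or from BDNF-treated donors (n = 3), and their RNA was sequenced. The 24 small RNA libraries fall into batches x and z and the 18 hippocampal libraries into batches a to d, and the EV-treated libraries lie in batches a and b. The lysates held 4576020 to 10275409 miRNA counts, while the control EV libraries held 439469 to 3952332 and the BDNF EV libraries 377730 to 2712551. Hippocampal libraries held 16274937 to 36835780 gene counts. No label says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

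The question asked of the donor cells was which miRNAs the vesicles carried and whether BDNF altered them. On average the most abundant miRNA in both kinds of sample was miR-9-5p, a miRNA of neurons and neural progenitors, although in batch z miR-128-3p led in 5 of the 6 EV libraries. The share of miR-9-5p was 39.1% ± 2.04 (SD, n = 6) of the counts in control lysates and 14.7% ± 3.87 (SD, n = 6) in control EVs. It was followed in the EVs by the neuronal miR-128-3p with 11.7% ± 1.87, let-7c-5p with 8.68% ± 1.77, miR-7a-5p with 7.67% ± 1.29 and let-7f-5p with 7.17% ± 1.02 (SD, n = 6). After BDNF miR-9-5p held 16.0% ± 5.34 of the EV counts and 40.1% ± 1.57 of the lysate counts (SD, n = 6), and miR-128-3p held 13.1% ± 2.17 and 10.2% ± 2.90.

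EVs of control cultures were much richer than their lysates in miR-122-5p, the dominant miRNA of liver. Its level was 5969 ± 3462 CPM (normalised counts scaled to a common total) in EVs and 52.4 ± 13.8 in lysates (SD, n = 6 each, all 24 libraries normalised together), a fold of 93.1 (95% interval 51.2 to 169). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (hereafter edgeR adjusted p) its log2 fold change was 6.54 ± 0.44 (SE, edgeR adjusted p = 2.92e-11), and it was 5.60 within batch x and 7.59 within batch z. The precursor of miR-122-5p lies at chromosome 18, 65248861 to 65248926 (GRCm38.p6). The erythrocyte miR-451a rose by 2.64 ± 0.40 (log2, SE), the leukocyte miR-142a-5p by 3.73 ± 0.31, miR-1a-3p of muscle by 2.69 ± 0.51 and the smooth muscle miR-143-3p by 1.89. For miR-1a-3p control EV 7 stood at 591 CPM and the other control EVs at 41.8 to 74.7, and without control EV 7 the rise was 1.46 ± 0.23. Among neuronal miRNAs, miR-485-5p rose by 1.97 ± 0.14, miR-494-3p by 1.91 and miR-124-3p by 1.30 ± 0.19 (edgeR adjusted p = 1.76e-06). Further miRNAs that rose were miR-214-3p (3.78), miR-5121 (2.68), miR-3535 (2.21), miR-103-3p (2.04) and miR-129-2-3p (574 CPM in EVs, 152 in lysates). In the other direction, miR-9-5p fell by 1.95 ± 0.15 (log2, SE, edgeR adjusted p = 1.59e-10), with −1.60 in batch x and −2.39 in batch z. The passenger strand miR-16-1-3p fell by 2.80 ± 0.26, miR-32-5p by 2.54, miR-449a-5p by 2.50, miR-301a-5p by 2.13, miR-1964-3p by 2.07, let-7a-1-3p by 1.94, miR-450a-5p by 1.81, miR-486a-3p by 1.77 and miR-708-3p by 1.76. The homeobox-cluster miRNAs miR-10a-5p, with 13.8 ± 8.41 CPM in EVs against 0.132 in lysates, and miR-10b-5p, with 5.83 ± 3.59 against 0.527 ± 0.379, also passed, as did miR-150-5p of lymphocytes, with 2.77 against 0.0747. Their lysates held 3 counts per library or fewer on average, so no fold is given for them.

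Of the 521 miRNAs tested, 315 differed between control EVs and lysates, 167 higher and 148 lower in EVs, of which 85 and 87 by more than 2-fold. Without the filter on low counts the split was 135 higher and 213 lower, and the median of all miRNAs moved by −0.21 (log2). A log2 difference smaller than that, such as −0.02 of let-7c-5p, carries no direction independent of the scaling. Within batch x 339 miRNAs passed and within batch z 295.

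Among the fixed groups of miRNAs, those of cells other than neurons lay mostly on the EV side. Of 9 measured miRNAs of liver and serum, 8 rose and 1 fell in control EVs; besides miR-122-5p, miR-320-3p rose by 1.19, miR-192-5p by 1.30 and miR-423-5p by 1.06, while miR-375-3p of endocrine cells fell by 1.79. Of 9 blood and immune miRNAs 6 rose and 0 fell, among them miR-155-5p (1.48) and miR-486a-5p (0.76), and 3 did not pass. Of 22 glial, vascular and mesenchymal miRNAs 13 rose, 4 fell and 5 did not pass; miR-365-3p rose by 2.78, miR-145a-5p by 2.67 and miR-31-5p by 2.14, and miR-21a-5p fell by 1.56. These 3 groups passed limma's camera test (camera adjusted p = 0.00585, 0.0231 and 0.0366), which was lost in each with an estimated correlation (adjusted p = 0.299, 0.261 and 0.412 with an estimated correlation). The liver list shares miR-451a, miR-486a-5p and miR-10b-5p with the other lists. Of 10 let-7 members, the family that marks differentiated cells, 6 rose (let-7d-5p 0.89, let-7e-5p 0.69, let-7a-5p 0.60), 2 fell (let-7i-5p −1.08, miR-98-5p −0.29) and 2 did not pass (camera adjusted p = 0.422). Of 12 members of the miR-17-92 clusters, which promote proliferation, 7 rose, 0 fell and 5 did not pass (miR-19b-3p 1.35, miR-17-5p 0.99, camera adjusted p = 0.381), and miR-19b-3p lost the threshold without control EV 9 (edgeR adjusted p = 0.0750). Neuron-enriched miRNAs were divided, with 5 of 22 higher, 7 lower and 10 not passing (miR-129-1-3p 1.85, miR-488-3p −1.67, miR-129-5p −1.59, miR-153-3p −1.23, camera adjusted p = 0.705). The imprinted Dlk1-Dio3 cluster was divided too, with 11 of 34 higher, 10 lower and 13 not passing (miR-667-3p 1.54, miR-543-3p −1.59, miR-381-3p −1.50, camera adjusted p = 0.962). The miR-29 and miR-30 families had 3 of 9 higher, 3 lower and 3 not passing (miR-29b-3p −1.35, miR-30e-3p −1.05, camera adjusted p = 0.705), and their median was 0.04 while mean and test point down. Of 14 activity and BDNF regulated miRNAs 3 rose, 3 fell and 8 did not pass (camera adjusted p = 0.962; median −0.12, mean −0.01, test upward). Adjusted over the list alone, the counts in all 9 lists were the same as over all miRNAs tested. Among the miRNAs linked with the study, miR-132-5p fell by 1.02 and miR-218-5p by 0.47. miR-132-3p differed by 0.00 (edgeR adjusted p = 0.998) and miR-690 by −0.62 (edgeR adjusted p = 0.223; −1.19 in batch x, 0.33 in batch z).

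In BDNF-treated cultures too EVs held more miR-122-5p than lysates. Its level was 6670 ± 5163 CPM in EVs and 39.2 ± 3.76 in lysates (SD, n = 6 each), a log2 fold change of 7.11 ± 0.45 (SE, edgeR adjusted p = 6.96e-12; 5.74 in batch x and 8.10 in batch z). The erythrocyte miR-451a stood at 14.4 ± 11.9 CPM in EVs and passed, with no fold given since BDNF lysates held 2.33 counts of it per library on average. miR-142a-5p rose by 4.17, miR-3535 by 2.50, miR-3068-3p by 2.46, miR-5121 by 2.39, miR-485-5p by 2.16, miR-143-3p by 2.16, miR-192-5p by 2.06, miR-671-5p by 1.88, miR-1a-3p by 1.76 and miR-103-3p by 1.60. Lower in EVs were miR-449a-5p (−3.14), miR-32-5p (−2.71), miR-16-1-3p (−2.39), miR-301a-5p (−2.12), miR-450a-5p (−2.03), miR-212-5p (−1.78 ± 0.19), miR-132-5p (−1.76 ± 0.14), let-7a-1-3p (−1.73), miR-504-5p (−1.73) and miR-369-3p (−1.70), and miR-132-3p was lower by −0.99 ± 0.18 (log2, SE). miR-690 rose by 1.28 ± 0.42 (edgeR adjusted p = 0.0118), with −0.03 in batch x and 2.39 in batch z, so that the rise did not hold within batch x, and without BDNF EV 7 its edgeR adjusted p was 0.126. miR-218-5p differed by 0.02 (edgeR adjusted p = 0.872). In all, 298 of 521 miRNAs passed, 156 higher and 142 lower; the split was 120 and 204 without the filter, with a median shift of −0.28, and 128 and 174 with miR-9-5p left out, with a median shift of −0.14. Within batch x 309 passed and within batch z 267.

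Liver and serum miRNAs again led the groups in BDNF cultures, with 8 of 9 higher and 1 lower (camera adjusted p = 8.37e-05, against adjusted p = 0.109 with an estimated correlation). Of the blood and immune miRNAs 5 of 9 rose, 0 fell and 4 did not pass (camera adjusted p = 0.00548, against adjusted p = 0.109 with an estimated correlation). Adjusted over the list alone 7 of them rose. Of 10 let-7 members 8 rose, 1 fell and 1 did not pass (let-7k 0.94, let-7f-5p 0.91, camera adjusted p = 0.0528); let-7k lost the threshold without BDNF EV 1 (edgeR adjusted p = 0.0538) or 2 (0.0583). In the glial, vascular and mesenchymal group 12 of 22 rose, 3 fell and 7 did not pass (camera adjusted p = 0.0986; 14 rose adjusted over the list alone). Of the neuron-enriched miRNAs 6 of 22 rose, 9 fell and 7 did not pass (camera adjusted p = 0.311; 7 rose adjusted over the list alone). In the Dlk1-Dio3 cluster 7 of 34 rose, 13 fell and 14 did not pass (camera adjusted p = 0.732; 9 rose and 14 fell adjusted over the list alone). The activity list had 4 of 14 higher, 4 lower and 6 not passing (camera adjusted p = 0.732). In the miR-17-92 clusters 2 of 12 rose, 1 fell and 9 did not pass (camera adjusted p = 0.739). In the miR-29 and miR-30 families 2 of 9 rose, 4 fell and 3 did not pass (camera adjusted p = 0.732).

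In donor lysates 16 h after BDNF, the highest rise was that of miR-132-5p and its partner arm miR-132-3p rose about as much, both from miR-132, a miRNA induced through CREB downstream of neurotrophins. miR-132-5p stood at 331 ± 92.1 CPM after BDNF and 128 ± 18.3 in control lysates (SD, n = 6 each), a 2.57-fold rise (95% interval 2.36 to 2.79), and miR-132-3p at 986 ± 321 against 393 ± 32.6, a 2.44-fold rise (2.08 to 2.85). On the log2 scale these were 1.36 ± 0.06 (SE, edgeR adjusted p = 1.97e-10; 1.27 in batch x, 1.49 in batch z) and 1.29 ± 0.12 (edgeR adjusted p = 3.66e-06; 0.91 and 1.70). Both arms of miR-212, made from the same primary transcript (miR-132 precursor at chromosome 11, 75173682 to 75173747, and miR-212 precursor at 75173388 to 75173478, GRCm38.p6), rose with them. miR-212-3p rose by 1.28 ± 0.17 (edgeR adjusted p = 0.000241; 0.74 in batch x, 1.86 in batch z) and miR-212-5p by 0.79 ± 0.08 (edgeR adjusted p = 1.02e-05). miR-31-5p rose by 1.29 ± 0.15, from 4.58 to 11.1 CPM.

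Further rises in the lysates were smaller and included miR-369-3p (1.20), miR-376c-3p (0.74), miR-30b-5p (0.73), miR-19b-3p (0.73), miR-15a-5p (0.70), miR-20a-5p (0.67), miR-155-5p (0.63), miR-17-5p (0.61) and miR-135a-5p (0.60). miR-106a-5p (0.82, edgeR adjusted p = 0.0431) and the endothelial miR-126a-5p (0.71, edgeR adjusted p = 0.0263) also passed. The call of miR-106a-5p was lost without BDNF lysate 2, 3, 7, 8 or 9 or control lysate 1, 2, 7 or 8 (edgeR adjusted p = 0.0510 to 0.0983). The call of miR-126a-5p was lost without BDNF lysate 3 or 7 or control lysate 1, 2 or 7 (0.0508 to 0.0652). Of miRNAs with a mean of at least 20 CPM the lowest values belonged to miR-1964-3p (−0.78), miR-151-3p (−0.70), miR-129-5p (−0.64), miR-148a-3p (−0.64), miR-1198-5p (−0.63), miR-671-3p (−0.62), miR-1981-5p (−0.60), miR-708-3p (−0.58), miR-669c-5p (−0.58) and miR-5099 (−0.56), and all passed. The liver miR-122-5p fell by 0.37 (edgeR adjusted p = 0.0245), a call lost without BDNF lysate 2, 3 or 9 or control lysate 1, 2 or 7 (edgeR adjusted p = 0.0503 to 0.0695). miR-218-5p differed by 0.08 (edgeR adjusted p = 0.208) and miR-690 by −0.08 (edgeR adjusted p = 0.761).

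Of 519 miRNAs tested in lysates 224 passed, 115 higher and 109 lower after BDNF, and only 7, all higher, changed by more than 2-fold; the median size of the called changes was 0.40 (log2). The batches taken alone gave 112 calls in batch x and 133 in batch z, and the count was 122 without the batch term and 65 with all small RNA libraries in the fit. With 1 axis of spread between libraries of the same group and batch as a covariate it was 60, and the arms of miR-132 and miR-212 were among those that stayed.

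Activity and BDNF regulated miRNAs moved upward as a group in lysates, with 7 of 14 higher, 3 lower and 4 not passing (camera adjusted p = 4.49e-05, and adjusted p = 0.0158 with an estimated correlation). Adjusted over the list alone 8 were higher and 3 lower. Besides miR-132 and miR-212, miR-34a-5p rose by 0.78, miR-124-3p by 0.53 and the spine-size regulator miR-138-5p by 0.52, while miR-206-3p fell by 0.72, miR-485-5p by 0.40 and miR-134-5p, a brake on dendritic spine growth, by 0.20. That list holds miRNAs linked with the study and is not independent evidence of its direction. Neuron-enriched miRNAs rose in 10 of 22, fell in 5 and did not pass in 7 (miR-137-3p 0.45, miR-9-3p 0.43, miR-744-5p −0.43, miR-128-3p −0.29). The arms of miR-132 and miR-212 are in this list too (camera adjusted p = 0.0114, and adjusted p = 0.0400 with an estimated correlation), and adjusted over the list alone 10 rose and 6 fell. Of the miR-17-92 clusters 8 of 12 rose, 1 fell and 3 did not pass (miR-18a-5p 0.66, miR-25-3p −0.36, camera adjusted p = 0.0397, against adjusted p = 0.399 with an estimated correlation; 8 and 2 adjusted over the list alone). Of the let-7 family 0 of 10 rose, 5 fell and 5 did not pass (let-7i-5p −0.46, let-7c-5p −0.34, camera adjusted p = 0.0451, against adjusted p = 0.399 with an estimated correlation; 1 and 5 adjusted over the list alone).

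The remaining lists did not pass as groups in the lysates. Of the Dlk1-Dio3 cluster 13 of 34 rose, 10 fell and 11 did not pass (miR-154-5p 0.65, miR-431-5p 0.51, miR-541-5p −0.36, miR-379-5p −0.30, camera adjusted p = 0.324). Of glial, vascular and mesenchymal miRNAs 8 of 19 rose, 3 fell and 8 did not pass (miR-199a-3p 0.58, the oligodendrocyte miR-219a-2-3p −0.45, camera adjusted p = 0.274; 8 and 4 adjusted over the list alone). Of liver and serum miRNAs 1 of 7 rose, 3 fell and 3 did not pass (miR-194-5p 0.33, miR-192-5p −0.41, miR-320-3p −0.24, camera adjusted p = 0.117; 1 and 5 adjusted over the list alone). Of blood and immune miRNAs 3 of 6 rose, 1 fell and 2 did not pass (miR-16-5p 0.40, camera adjusted p = 0.682; 3 and 2 adjusted over the list alone). Of the miR-29 and miR-30 families 3 of 10 rose, 4 fell and 3 did not pass (miR-29a-3p 0.52, miR-30e-3p −0.54, miR-30d-5p −0.33, camera adjusted p = 0.963), with a median of 0.15 while the test points down.

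In the EVs none of the 377 miRNAs passed for BDNF against control donors by edgeR's quasi-likelihood test (0 calls, 43 at an unadjusted p under 0.05). DESeq2 called 12 (5 higher, 7 lower). The count was 14, with 2 higher and 12 lower, without control EV 2, 4 without control EV 7 and 2 without BDNF EV 9. The miRNAs nearest the threshold shared an edgeR adjusted p of 0.0844. Among them were miR-690 (1.38 ± 0.32 log2, SE; 0.81 in batch x and 2.41 in batch z), miR-132-5p (0.59 ± 0.16; 0.57 and 0.65) and miR-218-5p (0.53 ± 0.14; 0.58 and 0.55) on the higher side. On the lower side were miR-129-1-3p (−0.59 ± 0.15), miR-129-2-3p (−0.56 ± 0.14) and miR-485-3p (−0.39 ± 0.10). For miR-690 the edgeR adjusted p was 0.0120 without BDNF EV 9 and 0.0136 without control EV 2. Without control EV 2 miR-218-5p (edgeR adjusted p = 0.0215), miR-129-1-3p (0.0136), miR-129-2-3p (0.0136) and miR-485-3p (0.0215) passed too, and without control EV 7 miR-218-5p (0.0295), miR-129-1-3p (0.0469) and miR-129-2-3p (0.0316) passed. In CPM, miR-690 stood at 56.5 ± 25.0 in BDNF EVs and 19.3 ± 9.82 in control EVs, miR-132-5p at 94.3 ± 8.50 and 62.7 ± 15.6, and miR-218-5p at 5592 ± 676 and 3795 ± 881 (SD, n = 6 each). miR-132-3p differed by 0.31 ± 0.12 (edgeR adjusted p = 0.325), at 494 ± 55.0 and 392 ± 86.9 CPM.

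No member of the 9 lists passed over all miRNAs tested in this EV comparison. Adjusted over the list alone, 3 of 13 activity and BDNF regulated miRNAs passed, all higher, and the list had a median log2 fold change of 0.29 (camera adjusted p = 0.00116, against adjusted p = 0.206 with an estimated correlation). The 3 are miRNAs linked with the study, so this is not independent evidence. Of 22 neuron-enriched miRNAs 2 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.296). In the other 7 lists 0 passed when adjusted over the list alone. Their camera adjusted p was 0.886 for the Dlk1-Dio3 cluster and for let-7, 0.645 for the miR-17-92 clusters and the glial, vascular and mesenchymal group, 0.933 for blood and immune, 0.981 for liver and serum (median −0.07, mean 0.02) and 0.911 for the miR-29 and miR-30 families. Over 366 miRNAs tested on simulated counts, 40.7% of 27 changed 1.5-fold were recovered, 92.6% of 27 at 2-fold and 100% of 23 at 4-fold. Sparser changes were not simulated.

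**Figure D1:**
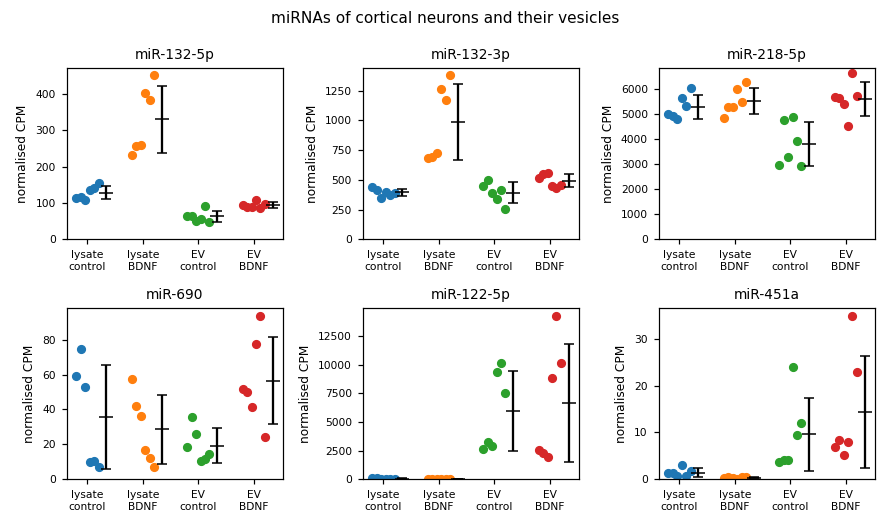
Normalised CPM (linear axes from 0) of miR-132-5p, miR-132-3p, miR-218-5p, miR-690, miR-122-5p and miR-451a in control and BDNF lysates and control and BDNF EVs, with 1 point per library and the mean ± SD of 6 libraries. miR-132-5p stands at 331 ± 92.1 in BDNF lysates against 128 ± 18.3 in control lysates.

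Whether BDNF acted differently on the EV and the lysate content was tested as the difference of its effects. The effect in EVs minus that in lysates was negative for miR-132-3p (−0.99 ± 0.24 log2, SE), miR-132-5p (−0.74 ± 0.20) and miR-31-5p (−1.19 ± 0.31), which had risen in lysates, and for miR-129-2-3p (−0.81 ± 0.19), miR-15b-5p (−0.86) and miR-329-3p (−0.73). Positive differences were found for miR-451a and miR-1949, both at few counts in some groups (2.33 of miR-451a per BDNF lysate and 3.50 of miR-1949 per control EV library on average), miR-3081-3p (0.99 ± 0.22), miR-1843a-5p (0.78), miR-1843b-5p (0.77), let-7i-5p (0.69 ± 0.15), miR-30e-3p (0.64) and miR-370-3p (0.57). For let-7i-5p the levels were 25270 CPM in BDNF EVs and 22086 in control EVs, and 33211 in BDNF lysates and 46678 in control lysates. These 14 of 521 passed (8 positive, 6 negative; edgeR adjusted p = 0.0203 for let-7i-5p and miR-3081-3p, 0.0364 for miR-129-2-3p and 0.0382 for miR-132-3p, miR-132-5p and miR-451a; 81 at an unadjusted p under 0.05). For miR-690 the difference was 1.91 ± 0.60 (edgeR adjusted p = 0.0914) and for miR-218-5p 0.50 ± 0.17 (edgeR adjusted p = 0.115; 0.0379 without control EV 2). With the replicate number as a block none of the 14 passed (0 calls by edgeR, 70 at an unadjusted p under 0.05), with an edgeR adjusted p of 0.0515 to 0.0877 for the 14. DESeq2 called 35, and batch x alone gave 22 and batch z alone 3.

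Single libraries moved this count of 14 miRNAs whose BDNF effect differed between EVs and lysates. It was 0 without control EV 1, 8 without control EV 3, 5 without BDNF EV 8 and 7 without BDNF EV 9. Leaving out a BDNF lysate gave 7 (lysate 3), 6 (lysate 7), 5 (lysate 8) and 4 (lysate 9), and leaving out a control lysate gave 5 (lysates 1, 2 and 8) and 4 (lysate 7). Without control EV 1 the lowest edgeR adjusted p among the calls was 0.0637, and let-7i-5p, miR-3081-3p, miR-1843a-5p and miR-1843b-5p lost the threshold without that library alone. The other named calls were lost without several libraries each, with an edgeR adjusted p in those fits of 0.0528 to 0.0684 for miR-132-3p, 0.0539 to 0.0807 for miR-132-5p, 0.0516 to 0.0723 for miR-451a, 0.0528 to 0.102 for miR-30e-3p and 0.0548 to 0.251 for miR-370-3p. No list passed camera for the difference of effects. Of 22 neuron-enriched miRNAs 3 passed, all negative (camera adjusted p = 0.336), and adjusted over the list alone 3 were positive and 5 negative. Of 14 activity miRNAs 2 passed, both negative (camera adjusted p = 0.223), and adjusted over the list alone 2 were positive and 3 negative. The Dlk1-Dio3 cluster had 1 negative of 34 (2 positive and 1 negative adjusted over the list alone, camera adjusted p = 0.603) and let-7 had 1 positive of 10 (3 positive adjusted over the list alone, camera adjusted p = 0.0674). The miR-29 and miR-30 families had 1 positive of 9 (2 positive and 2 negative adjusted over the list alone, camera adjusted p = 0.603). With the same counts adjusted over the list alone, 1 of 9 was positive in each of the blood and immune (camera adjusted p = 0.603) and the liver and serum lists (0.190). In the glial, vascular and mesenchymal list 1 of 22 was negative (camera adjusted p = 0.222), and in the miR-17-92 clusters 0 of 12 passed (0.0674).

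In hippocampal neurons the question was which transcripts BDNF itself altered and whether EVs from BDNF-treated donors altered the same ones. BDNF (50 ng/ml for 20 min, the time of lysis not being given in the sources used here) raised Gal and Npy most among genes with a mean of at least 2 CPM. Gal, which encodes galanin, stood at 6.33 ± 1.75 CPM after BDNF and 0.202 ± 0.106 in controls (SD, n = 6 each; 5.17 counts per control library on average), a 27.7-fold rise (95% interval 20.1 to 38.2). Its log2 fold change was 4.79 ± 0.24 (SE, edgeR adjusted p = 1.44e-11), with 5.14 in batch b and 5.10 in batch c. Npy, which encodes neuropeptide Y, stood at 58.7 ± 8.65 against 7.60 ± 1.71 CPM, a 7.83-fold rise (95% interval 6.98 to 8.79, edgeR adjusted p = 3.94e-15). On the log2 scale it was 3.04 in batch b and 2.76 in batch c. Nnat, the imprinted neuronatin gene, rose 2.66-fold (2.48 to 2.85; edgeR adjusted p = 3.94e-15), to 3016 ± 449 from 1139 ± 204 CPM. Lgals1, encoding galectin, rose to 42.1 from 14.8 CPM (log2 1.54 ± 0.09), and Crhbp, which binds corticotropin-releasing hormone, to 25.0 from 8.27 CPM (log2 1.66 ± 0.25, edgeR adjusted p = 0.00101). Within batch b Crhbp differed by 1.55 (edgeR adjusted p = 0.192). Kera, a corneal proteoglycan gene, fell by 1.76 ± 0.16, to 1.04 from 3.44 CPM, and Fst, the activin antagonist follistatin, by 1.22 ± 0.09.

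Also among the most raised were the bombesin-type receptor Nmbr (1.55), Fibcd1 (1.52), St8sia5 (1.32), the Ras effector Rin1 (1.29 ± 0.07) and Grp (1.25), all in log2. Vip rose by 1.53 ± 0.31 at mean counts per library of 12.5 with BDNF and 4.0 in controls. It did not pass in batch b (edgeR adjusted p = 0.0965) or c (0.0644). Among the most lowered were the vasopressin receptor Avpr1a (−1.47 ± 0.13), Klhl14 (−1.32), Unc13c (−0.97), Olfm4 (−0.90), adenosine deaminase Ada (−0.87), the neurofilament-type Prph (−0.84), Fam19a1 (−0.83) and Gpc3 (−0.82). Of 17609 genes tested 2422 passed, 1321 higher and 1101 lower, of which 71 and 17 by more than 2-fold. Batch b alone gave 833 and batch c alone 1213, and the count was 1537 without the 3 libraries of highest Gm42418 (control sets 2 and 4, control EV set 1), a gene that overlaps ribosomal RNA, and 843 without the batch term.

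The late activity and BDNF response genes rose in 8 of 21 measured members and fell in 1, with 12 not passing (camera adjusted p = 2.39e-11, against adjusted p = 0.256 with an estimated correlation; the same counts adjusted over the list alone). Besides Npy, the synaptic pentraxin Nptx2 rose by 1.08 ± 0.16 (edgeR adjusted p = 0.000454), with 0.42 in batch b (edgeR adjusted p = 0.181) and 1.44 in batch c. The neurotrophin-inducible Vgf rose by 1.03 ± 0.20, Cort by 0.97, Penk by 0.94, Tac1 by 0.80, Sst by 0.76 and Inhba by 0.53, and Pdyn fell by 0.27. ERK pathway feedback targets rose in 11 of 16 and fell in 1 (12 and 1 adjusted over the list alone). The camera adjusted p was 4.51e-08, against adjusted p = 0.256 with an estimated correlation. Dusp5 was at 0.76, Dusp6 at 0.65, Spred3 at 0.58, Etv5 at 0.45, Ccnd1 at 0.36 and Etv1 at −0.24. For Dusp6 the edgeR adjusted p was 0.0505 without the 3 libraries of highest Gm42418, and for Dusp5 it was 0.0576 without BDNF 6 and 0.0587 without control 6. Of 20 immediate early genes 1 rose, 0 fell and 19 did not pass (the same adjusted over the list alone, camera adjusted p = 0.308). The dendritic Arc rose 2.13-fold (95% interval 1.66 to 2.71), to 10.3 ± 2.52 from 4.97 ± 1.66 CPM. Its log2 fold change was 1.09 ± 0.18 (edgeR adjusted p = 0.000879), with 0.50 in batch b (edgeR adjusted p = 0.305) and 1.46 in batch c. Fos differed by −0.86 (edgeR adjusted p = 0.34) and Npas4 by −0.84 (edgeR adjusted p = 0.40).

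Genes of proliferation moved upward after BDNF. Of 20 measured progenitor and proliferation genes 14 rose, 0 fell and 6 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 1.31e-18, against adjusted p = 0.253 with an estimated correlation). Mki67, expressed in cycling cells, rose 1.73-fold, to 62.5 ± 20.5 from 35.4 ± 8.22 CPM (log2 0.79 ± 0.10; edgeR adjusted p = 0.000140), with 0.38 in batch b and 1.10 in batch c. The mitotic cyclin Ccnb1 rose by 0.88 ± 0.10 (0.47 in batch b with edgeR adjusted p = 0.111), Cdk1 by 0.75, Cenpf by 0.75, Top2a by 0.67 and the progenitor filament Nes by 0.27.

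Synaptic genes rose in part. Of 31 excitatory synapse and postsynaptic density genes 9 rose, 3 fell and 19 did not pass (11 and 3 adjusted over the list alone, camera adjusted p = 0.00252, against adjusted p = 0.641 with an estimated correlation). Dlg4, the scaffold PSD-95, rose by 0.45 ± 0.03 (edgeR adjusted p = 5.50e-09), to 574 ± 20.7 from 421 ± 13.4 CPM, and the AMPA receptor auxiliary protein Cacng8 by 0.35, while Camk2b fell by 0.19, Homer3 by 0.15 and Nlgn1 by 0.11. Of 29 presynaptic genes 9 rose, 1 fell and 19 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.00115, against adjusted p = 0.641 with an estimated correlation). The vesicular glutamate transporter Slc17a7 rose by 0.43 and its relative Slc17a6 fell by 0.27; Nrxn3 rose by 0.43, the vesicular GABA transporter Slc32a1 by 0.32 and Syt1 by 0.21. Of 36 dendrite growth and cytoskeleton genes 4 rose, 7 fell and 25 did not pass (6 and 8 adjusted over the list alone, camera adjusted p = 0.796). The guidance cues Sema3a and Slit2 rose by 0.55 and 0.43 and Map1a by 0.33, while Dpysl3 fell by 0.22 and Mapt by 0.21.

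Markers of neuron classes moved in both directions. Of 13 inhibitory markers 3 rose, 1 fell and 9 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.189). The GABA-synthesis genes Gad2 and Gad1 rose by 0.37 and 0.29 and the calretinin gene Calb2 fell by 0.77 ± 0.06. Of 13 excitatory markers 1 rose, 4 fell and 8 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.109). Tbr1 was at 0.15, Wfs1 at −0.27, Neurod6 at −0.24 and Emx1 at −0.19. The Neurod6 call was lost without the libraries of highest Gm42418 and without any library but BDNF 2 and control 2 or 3 (edgeR adjusted p = 0.0594 to 0.107), and its value was 0.01 in batch b. Among other cell types, 3 of 17 astrocyte markers rose and 3 fell (4 and 3 adjusted over the list alone; Aldh1l1 0.30, Acsbg1 0.24, Fgfr3 0.22, Gja1 −0.39, Gfap −0.22, Aqp4 −0.16, camera adjusted p = 0.731). Of 13 oligodendrocyte lineage markers 3 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.0461, against adjusted p = 0.641 with an estimated correlation). The precursor genes Cspg4 (0.24), Olig1 (0.20) and Pdgfra (0.16) rose, and the later genes Enpp6 (−0.92), Bcas1 (−0.62) and Mog (−0.48) fell. Of 6 microglial and macrophage markers 2 rose and 0 fell (the same adjusted over the list alone; Ptprc 1.02, Cd68 0.64, camera adjusted p = 0.161). Of 13 vascular and fibroblast markers 2 rose and 2 fell (3 and 2 adjusted over the list alone; Acta2 0.59, Col3a1 0.44, Dcn −0.67 ± 0.04, Rgs5 −0.21, camera adjusted p = 0.447; median −0.01, mean 0.06).

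Among genes of metabolism and stress, 9 of 28 nuclear oxidative phosphorylation genes rose after BDNF and 0 fell (13 and 0 adjusted over the list alone; Atp5b 0.17, Ndufb8 0.16, Cox5a 0.15, camera adjusted p = 0.0115, against adjusted p = 0.681 with an estimated correlation). Of 7 mitochondrially encoded genes 0 passed (also adjusted over the list alone, camera adjusted p = 0.738). Of 22 glycolysis and hypoxia genes 4 rose and 2 fell (5 and 2 adjusted over the list alone; Eno1 0.32, Aldoa 0.30, Pkm 0.19, Pfkfb3 −0.20, camera adjusted p = 0.171). Of 21 unfolded protein and integrated stress response genes 3 rose and 0 fell (4 and 0 adjusted over the list alone; Psat1 0.25, Hsp90b1 0.21, Calr 0.14, camera adjusted p = 0.0190, against adjusted p = 0.695 with an estimated correlation). For Psat1 the edgeR adjusted p was 0.0479, and 0.0741 with the replicate block. Of 24 cholesterol biosynthesis genes 1 rose and 0 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.0197, against adjusted p = 0.681 with an estimated correlation). Of 41 cytosolic ribosomal protein genes 0 rose and 3 fell (the same adjusted over the list alone; Rpl30 −0.23, Rpl5 −0.21, Rpl15 −0.17, camera adjusted p = 0.0605). Of 23 genes of extracellular vesicle biogenesis 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.639). The secretion GTPase Rab27b rose by 0.66, and Sdc1 fell by 0.22 (edgeR adjusted p = 0.0542 with the replicate block) and Tsg101 by 0.16. Of 18 interferon genes 1 rose (Ifit2 0.30, camera adjusted p = 0.447) and of 12 NF-kB and inflammatory genes 0 passed (camera adjusted p = 0.639), the same adjusted over the list alone, and no erythrocyte gene was measured (0). The calls of Dusp6, Ifit2, Neurod6, Psat1, Rpl5 and Sdc1 were lost without the 3 libraries of highest Gm42418. Rpl5 fell short without BDNF 4, 5 or 6 or control 4 or 6 (edgeR adjusted p = 0.0591 to 0.112). Sdc1 fell short without BDNF 2, 3, 4 or 6 or control 2, 3, 4 or 6 (edgeR adjusted p = 0.0625 to 0.105) and Psat1 without any but BDNF 3 and control 1 or 3 (0.0502 to 0.147). Ndufb8 was lost without BDNF 6 (edgeR adjusted p = 0.0662) or control 6 (0.0691) and Ifit2 without BDNF 4 (0.0519).

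After exposure to EVs from control donors few transcripts of hippocampal neurons differed from the controls. Mt2, the metallothionein that binds zinc and is induced by it, stood at 9.93 ± 2.74 CPM (SD, n = 3) after control EVs and 25.7 ± 8.09 (SD, n = 6) in controls, a fold of 0.415 (95% interval 0.357 to 0.483). Its log2 fold change was −1.27 ± 0.11 (SE, edgeR adjusted p = 3.39e-06), and −1.41 in batch b. Slc30a1, the zinc exporter of the plasma membrane and likewise induced by zinc, fell by 0.44 ± 0.06, to 28.6 ± 0.979 from 40.01 ± 2.38 CPM (edgeR adjusted p = 0.00262). Within batch b its value was −0.44 (edgeR adjusted p = 0.130), and without control EV set 2 its edgeR adjusted p was 0.0572. Slc39a10, a zinc importer, rose by 0.40 ± 0.04, to 186 ± 7.89 from 140 ± 3.88 CPM (edgeR adjusted p = 9.90e-06; 0.43 in batch b). The predicted gene Gm45774, whose values run with those of Mt2 over the libraries and which may share its reads, fell by 1.09 ± 0.11 (edgeR adjusted p = 6.79e-06; −1.30 in batch b). 6330403K07Rik fell by 0.25 ± 0.05 (edgeR adjusted p = 0.0434). That call was lost with the replicate block (edgeR adjusted p = 0.129), without control 1 (0.285), control 3 (0.149) or control 4 (0.0668), and without control EV set 1 (0.287), 2 (0.355) or 3 (0.207). In GRCm38.p6 Mt2 lies at chromosome 8, 94172618 to 94173567, Slc30a1 at chromosome 1, 191906697 to 191913248, and Slc39a10 at chromosome 1, 46807544 to 46925776. The metallothionein gene Mt1 beside Mt2 differed by −0.51 (edgeR adjusted p = 0.776) and the brain metallothionein Mt3 by −0.09.

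These 5 of 17609 genes passed for control EVs against control, 1 higher and 4 lower (1082 at an unadjusted p under 0.05), and DESeq2 called 6. Without the batch term Mt2 differed by −1.37 (edgeR adjusted p = 0.831), while Slc39a10 and Slc30a1 passed, and 2 genes passed in all. Without control EV set 2 the count was 3. Batches c and d hold no EV-treated libraries. Genes nearest the threshold were Ifi203 (0.78, edgeR adjusted p = 0.594), Plxna4os3 (0.76, 0.201) and Pcdh7 (0.22) on the higher side. On the lower side were the Notch modifier Lfng (−0.36), the Wnt regulator Nkd1 (−0.41) and Wnt7b (−0.21). The edgeR adjusted p of Lfng was 0.0552, and 0.0354 without control 1 and 0.0483 without control 6.

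No member of the 23 gene lists passed over all genes for control EVs. By camera with the preset correlation 8 lists passed, and 0 with an estimated correlation. On the lower side were immediate early genes (camera adjusted p = 4.07e-06), cholesterol biosynthesis and proliferation (both 3.00e-07), oxidative phosphorylation (0.000336), oligodendrocyte lineage (0.000593) and vascular markers (0.0278). The unfolded protein and stress response was on the higher side (camera adjusted p = 1.19e-05). For these 7 lists the adjusted p was 0.6252 with an estimated correlation. The astrocyte markers had a median of −0.04 (camera adjusted p = 0.0357, against adjusted p = 0.654 with an estimated correlation). Adjusted over the list alone, 2 astrocyte markers were lower (Aldh1l1 −0.30, Ntsr2 −0.70), 1 excitatory marker higher (Prox1 0.16) and 2 lower (Pou3f1 −0.34, Neurod2 −0.25), 1 postsynaptic gene lower (Baiap2 −0.22) and 1 proliferation gene lower (Cdk1 −0.45), and 0 passed in each of the other lists.

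After EVs from BDNF-treated donors 4 of these 5 genes differed from the controls in the same direction. Mt2 stood at 10.6 ± 3.15 CPM (SD, n = 3), a fold of 0.442 (95% interval 0.381 to 0.513, log2 −1.18 ± 0.11, edgeR adjusted p = 2.69e-06). Within batch b its log2 fold change was −1.36. Slc30a1 fell by 0.55 ± 0.06, to 26.6 ± 1.08 CPM (edgeR adjusted p = 6.48e-05, −0.50 in batch b). Slc39a10 rose by 0.46 ± 0.04, to 195 ± 3.99 CPM (edgeR adjusted p = 1.29e-06; 0.44 in batch b), and Gm45774 fell by 1.18 (edgeR adjusted p = 1.32e-06; −1.39 in batch b). These 4 genes passed, 1 higher and 3 lower (1277 at an unadjusted p under 0.05). DESeq2 called 31, 5 higher and 26 lower, batch b alone gave 114, batches a and b together 12, the BDNF EV and control libraries alone 235 and all genes without the filter 156. Without the batch term 2 passed and Mt2 differed by −1.28 (edgeR adjusted p = 0.826). Nearest the threshold were the calcium channel Trpv6 (0.64, edgeR adjusted p = 0.0968), Dpp7 (0.35, 0.125) and Sema3c (0.30, 0.152), and on the lower side A830018L16Rik (−0.37, 0.0706), Islr (−0.37, 0.0706) and the basement membrane gene Nid1 (−0.48, 0.0968). A830018L16Rik passed without BDNF EV set 1 (edgeR adjusted p = 0.0478), Islr without control 6 (0.00904) and Nid1 without control 5 (0.0428). Mt1 differed by −0.63 (edgeR adjusted p = 0.298).

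Activity genes lay lower after BDNF EVs without passing over all genes. Of 20 immediate early genes 0 passed over all genes and 16 were lower when adjusted over the list alone, with a median of −1.0 (Npas4 −4.50, Fos −3.52, Egr4 −2.14, Egr3 −0.68, camera adjusted p = 1.63e-26, against adjusted p = 0.0594 with an estimated correlation). Fos stood at 7.66 ± 2.22 CPM after BDNF EVs (SD, n = 3), 44.3 ± 46.6 after control EVs (SD, n = 3) and 124 ± 83.3 in controls (SD, n = 6), where single libraries ran from 25.6 to 228. The mean log2 CPM of the immediate early genes in sets 1, 2 and 3 was 3.97, 5.38 and 5.86 in controls, 3.03, 5.24 and 4.42 after control EVs and 3.07, 3.50 and 3.77 after BDNF EVs. Of 21 late activity genes 8 were lower adjusted over the list alone (Ptgs2 −1.54, Pcsk1 −1.11, Rgs4 −0.57, camera adjusted p = 3.15e-11, against adjusted p = 0.138 with an estimated correlation). Vascular and fibroblast markers were the list that held with an estimated correlation (camera adjusted p = 2.14e-08; adjusted p = 0.0346 with an estimated correlation). Their median was −0.26, and 3 of 13 were lower adjusted over the list alone, the contractile genes Acta2 (−1.26) and Tagln (−1.20) and the endothelial receptor Kdr (−0.59).

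Further lists that passed the preset camera test for BDNF EVs did not hold with an estimated correlation. Of 13 oligodendrocyte lineage markers 6 were lower adjusted over the list alone (Bcas1 −0.40, Gpr17 −0.32, camera adjusted p = 1.88e-08, against adjusted p = 0.0594 with an estimated correlation). The same held for 2 of 12 NF-kB and inflammatory genes (Cxcl1 −1.97, Tnfaip3 −0.69, camera adjusted p = 4.75e-07, against adjusted p = 0.0594 with an estimated correlation). Of 7 mitochondrially encoded genes 1 was higher adjusted over the list alone (mt-Nd2 0.26, camera adjusted p = 3.22e-05, against adjusted p = 0.260 with an estimated correlation). Of 17 astrocyte markers, with a median of −0.07, 1 was lower (Gfap −0.33, camera adjusted p = 0.0393, against adjusted p = 0.599 with an estimated correlation). With 0 members adjusted over the list alone, the stress response (camera adjusted p = 0.000812), proliferation (0.00679) and ERK feedback (0.0184) lists passed downward, and each had an adjusted p of 0.599 with an estimated correlation. The interferon list passed downward (camera adjusted p = 0.0389, against adjusted p = 0.138 with an estimated correlation). Upward were the postsynaptic list (camera adjusted p = 0.000812), the excitatory markers (0.0306), both with adjusted p = 0.543 with an estimated correlation, and the dendrite growth list (0.0393, against adjusted p = 0.601 with an estimated correlation). Of the lists that did not pass, the inhibitory markers had 1 lower member adjusted over the list alone (Calb2 −0.29, camera adjusted p = 0.486) and the others 0.

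The direct comparison of BDNF EVs with control EVs asked what the BDNF treatment of the donors added. None of the 17609 genes passed (0 calls by edgeR, 1475 at an unadjusted p under 0.05, 0 by DESeq2), while batch b alone gave 118 calls and the fit without the filter on low counts 167. Near the threshold on the lower side were Ifi203 (−1.17 log2, edgeR adjusted p = 0.120) and the oxidoreductase Ero1l (−0.44, 0.311). On the higher side were Ppia (0.41, edgeR adjusted p = 0.311), Wnt7b (0.22, 0.349) and the pseudogene Gm13886 (1.30, 0.349). Ifi203 passed without BDNF EV set 1 (1 call; edgeR adjusted p = 0.0250). Mt2 differed by 0.09 (95% interval −0.16 to 0.34) and Slc39a10 by 0.07 between the EV groups. On simulated counts 73.1% of genes changed 1.5-fold and 95.5% at 2-fold were recovered (17378 genes). Sparser changes were not simulated and are not excluded.

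By camera 11 lists passed between the EV groups and 0 with an estimated correlation. The unfolded protein and stress response was lower, with 5 of 21 adjusted over the list alone (Ddit3 −0.72, Xbp1 −0.31, Asns −0.31, and Atf4 and Chac1, camera adjusted p = 5.10e-12, against adjusted p = 0.314 with an estimated correlation). So were late activity genes (1 adjusted over the list alone, Ptgs2 −2.22, camera adjusted p = 7.37e-09), NF-kB genes (3, Cxcl2, Tnfaip3 and Cxcl1; 0.00420), vascular markers (0; 0.00484) and interferon genes (1, Cxcl10; 0.0429), each with adjusted p = 0.314 with an estimated correlation. Immediate early genes were lower too (0 adjusted over the list alone, camera adjusted p = 7.37e-09, against adjusted p = 0.321 with an estimated correlation). Cholesterol biosynthesis was higher (0 adjusted over the list alone, camera adjusted p = 1.28e-09, against adjusted p = 0.314 with an estimated correlation). So were the excitatory markers (2 adjusted over the list alone, Pou3f1 0.34 and Neurod2 0.32, camera adjusted p = 0.00420, against adjusted p = 0.321 with an estimated correlation). With 0 adjusted over the list alone, oxidative phosphorylation (camera adjusted p = 0.00473) and mitochondrially encoded genes (0.0328) were higher too, both with adjusted p = 0.587 with an estimated correlation, as was the postsynaptic list (0.0357, against adjusted p = 0.632 with an estimated correlation). Of the lists that did not pass, the astrocyte markers had 1 higher member adjusted over the list alone (Fabp7 0.22, camera adjusted p = 0.925) and the others 0.

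**Figure D2:**
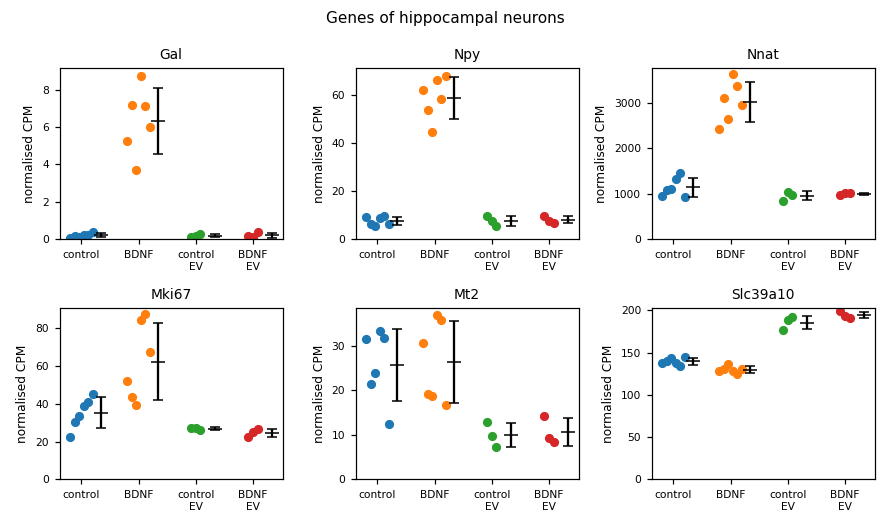
Normalised CPM (linear axes from 0) of Gal, Npy, Nnat, Mki67, Mt2 and Slc39a10 in hippocampal neurons left as controls, given BDNF, control EVs or BDNF EVs, with 1 point per library and the mean ± SD. Mt2 stands at 9.93 ± 2.74 after control EVs and 10.6 ± 3.15 after BDNF EVs against 25.7 ± 8.09 in controls.

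The change from control EVs to BDNF EVs was set against the change from control to BDNF over 17609 genes. Pearson's r was 0.0249 and Spearman's rho −0.0034 across genes, which are not independent replicates, and 5 of the 10 splits of the EV libraries gave an r as large in size, other assignments ranging from −0.0797 to 0.0797. The calls against the shared controls overlapped in 4 genes for control EVs and BDNF EVs, Slc39a10 upward and Mt2, Slc30a1 and Gm45774 downward. Unchanged groups simulated against the same controls gave 0.3 upward and 0 to 0.1 downward calls on average. Their overlap of 0 over 10 simulations thus decides nothing. With the controls split between the comparisons the overlap was 4 (1 up, 3 down) and 3 (1 up, 2 down). The correlation of the fold changes was 0.389 against 0.417 simulated, and the covariance 0.0156 against 0.0123 simulated; with the controls split r was 0.102 and 0.0403.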

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

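Of the tests in this part, the relation of outside miRNAs with library depth was chosen before its result was seen, whereas the tests by thinning, astrocyte markers, Gm42418, the 2 EV groups, the axis of spread, single batches and other splits of the samples were chosen after.

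In 10 of 214 groups of libraries that were checked, the highest or the lowest library stood apart from the rest of its group, and chance marks about 1 in 20 groups, here 10.7. Gm42418, which overlaps ribosomal RNA, stood at 19634.5 CPM in control 4 and 367 to 3656 in the other controls. Among the BDNF libraries, Kera was 1.95 CPM in set 1 (0.631 to 0.964 in the others), A830018L16Rik 32.1 in set 2 (24.8 to 27.0), Dpp7 12.8 in set 4 (13.7 to 14.1) and Gpc3 5.87 in set 5 (3.35 to 4.22). Dpp7 was also apart in control 1, with 16.0 against 12.3 to 13.6 CPM. BDNF EV 8, the shallowest library, held 2.68 CPM of miR-212-3p (21.4 to 31.1 in the others), 42.9 of miR-671-3p (19.5 to 26.0) and 1009.7 of miR-708-3p (470 to 621). In control EV 8 miR-129-5p stood at 4183 CPM, against 2260 to 2919.

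The effect of BDNF differed between EVs and lysates, by the test of the difference itself, for 14 miRNAs, of which 0 passed with the replicate block and 0 without control EV 1. The difference of log2 fold changes (EV minus lysate) was −1.19 for miR-31-5p, −0.99 for miR-132-3p, −0.86 for miR-15b-5p, −0.81 for miR-129-2-3p, −0.74 for miR-132-5p and −0.73 for miR-329-3p. It was 2.53 for miR-451a and 2.44 for miR-1949, fitted at few counts, and 0.99 for miR-3081-3p, 0.78 for miR-1843a-5p, 0.77 for miR-1843b-5p, 0.69 for let-7i-5p, 0.64 for miR-30e-3p and 0.57 for miR-370-3p.

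The first pattern is the higher level of liver, serum and blood miRNAs in EV libraries. With lysates thinned to EV totals the log2 fold change of miR-122-5p was 6.40, against 6.54, but thinning keeps expected shares, so depth stays open. A constant outside source, for example serum left from the plating medium, could raise these miRNAs most where few vesicles were collected. Over 12 such miRNAs, r of their mean log2 CPM with the log2 total counts was −0.610 within batch x (exact permutation p = 0.196, rho −0.429, p = 0.419, 6 libraries) and 0.0189 within batch z (exact permutation p = 0.975, rho −0.257, p = 0.658, 6 libraries). The adjusted values over these 2 relations were 0.392 and 0.975, r was −0.719 and −0.924 without the 2 libraries farthest in depth, and the value in batch z met the bound set against such a source (0 or above) but not beyond its spread, so an outside source and release by the cultured cells cannot be told apart with 6 libraries a batch.

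The second pattern is that of Mt2 and Slc30a1, lower, and Slc39a10, higher, after both kinds of EV, with Mt2 below the same-numbered control in 3 of 3 sets of each EV group. Fewer astrocytes are argued against by their markers, whose median was −0.0710 log2 in the lower of both comparisons while Mt2 was at −1.18. The libraries of high Gm42418 are argued against by the Mt2 value without them, −1.15. Less zinc reaching the cells with any added preparation is a candidate explanation, and Mt2 differed by 0.0909 between BDNF EVs and control EVs (95% interval −0.16 to 0.34). No group given a preparation without vesicles was analysed here, so vesicles and the rest of the preparation cannot be told apart, and control 6, at 12.4 CPM of Mt2, lay within the 7.29 to 14.2 CPM of the EV-treated libraries.

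The third pattern is the many small miRNA changes in lysates after BDNF. Depth is argued against, since thinning the lysates to EV totals left 159 calls (141 to 169 over 11 draws). An axis that held 33.5% of the spread between lysates of the same group and batch overlapped with the BDNF effect, with BDNF lysates at −6.30 to 0.409 on it and controls at −2.35 to 8.62, and its weights correlated with the fold changes across 519 miRNAs (r = −0.676, rho = −0.716, where the sign of an axis is arbitrary and miRNAs are not independent replicates). With this axis as a covariate each of the 4 arms of miR-132 and miR-212 passed, the lowest at 0.99 log2, which argues against the axis as the cause of their rise, and induction by BDNF remains the hypothesis for them. Of the other 220 calls 54 passed, so most may follow the axis, although an axis that carries part of a BDNF effect could remove it as well, and this stays open.

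Other splits of the libraries into groups of the same sizes were tested for each count of calls, the real split included. As many arose in 1 of 100 splits for EV against lysate in control (315, highest other 180) and BDNF cultures (298, highest other 115). It was 1 of 69 for BDNF in lysates (224, highest other 128) and in hippocampal neurons (2422, highest other 401). These are the lowest shares possible and argue against chance there. For the difference of effects it was 1 of 100 (14, highest other 1). This argues against chance for the unpaired fit alone, since 0 passed with the replicate block. Among the 32 splits that exchange members of as many same-numbered pairs the highest other was 70 for lysates and 636 for hippocampal neurons. For BDNF in EVs the real count of 0 is reached by any split (69 of 69, highest other 1) and decides nothing. For control EV against control 6 of 84 splits gave 5 calls or more (highest other 283), and chance cannot be excluded; the split with 283 sets controls 2 and 3 and control EV 2, all of batch b, against the rest, which points to a structure of the samples. For BDNF EV against control 4 of 84 gave 4 or more (highest other 113), under 0.05 of the splits, but the split with 113 exchanges controls 1 to 3 with the BDNF EV libraries and so follows batches a and b, in which it sets the same libraries against each other as the real split. Within batch b Mt2 was at −1.36, Slc30a1 at −0.50 and Slc39a10 at 0.44. Among the 8 splits that exchange members of same-numbered sets, 1 gave as many for control EV (highest other 4) and 2 for BDNF EV (highest other 113), and 8 splits are too few for a share under 0.05. For BDNF EV against control EV 10 of 10 splits gave 0 calls (highest other 0), and 10 splits are too few for a share under 0.05. Counted instead at an unadjusted p under 0.05, as many arose in 5 of 100 splits for the difference of effects (81, highest other 143), 4 of 69 for BDNF in EVs (43, highest other 56), 28 of 84 for control EV (1082, highest other 2791) and 16 of 84 for BDNF EV against control (1277, highest other 2532), so by this count chance cannot be excluded there. It was 2 of 10 for BDNF EV against control EV (1475, highest other 1603) and 1 for each of the others.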

How the results depend on the processing

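Single batches, libraries left out for depth or for Gm42418, thinning, the axis of spread, split controls and the CPM minimum for the correlation were tests chosen after the data were seen, whereas the others were planned.

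EV libraries were the shallowest and limit what can be said of BDNF in EVs, where 40.7% of simulated 1.5-fold changes were recovered. Counts for EV against lysate kept within 1.5 times of 315 and 298 in every setting tried: 300 to 321 and 281 to 302 with 1 library left out, 252 and 243 with thinned lysates, 339 and 323 by DESeq2. Lysate numbers are not taken to pair with EV numbers, since 1 and 2 of 6 pairs correlated above 0.1 (4 and 1 of 6 within batches) and 3 and 2 of 6 libraries correlated best with their own number, and with the replicate block the counts were 305 and 287. The block gave 238 calls for lysates and 2153 for hippocampal BDNF, took the 14 differences of effects to 0, ended the calls of Sdc1, Psat1 and 6330403K07Rik, and changed no other call reported. Of 4887 values of 208 named results under alternatives, 4388 kept their direction and side of the threshold, 390 lost the threshold, 70 gained it and 39 turned direction.

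Counts that moved by more than 1.5 times were as follows, and where no reason is given the cause was not tested. At an adjusted p under 0.1, BDNF in EVs gave 7 calls (against 0), the difference of effects 25 (against 14) and BDNF EV against control 9 (against 4), by construction. DESeq2 gave 12, 35 and 31. Without the filter on low counts they were 9 for BDNF in EVs, 38 for control EV (against 5), 156 for BDNF EV, 167 for BDNF EV against control EV (against 0) and 12 for the overlap of calls (against 4). Without the batch term they were 122 for lysates (against 224), 0 for the difference of effects, 843 for hippocampal BDNF (against 2422), and 2 each for control EV, BDNF EV and their overlap. All small RNA libraries in 1 fit gave 65 calls for lysates and 1 for EVs. The fit of BDNF EV and control libraries alone gave 235. Without the shallow EV libraries the difference of effects gave 5. With the axis of spread the lysates gave 60, and without the libraries of high Gm42418 hippocampal BDNF gave 1537.

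Single batches hold fewer samples. Batch x gave 1 call in EVs, 112 in lysates and 22 for the difference of effects, and batch z 133 in lysates and 3 for the difference. Batch b gave 833 calls for hippocampal BDNF, 114 for BDNF EV and 118 for BDNF EV against control EV, batch c gave 1213 for hippocampal BDNF, and batches a and b together 1067 and, for BDNF EV, 12. With 1 library left out, counts ranged from 0 to 14 for BDNF in EVs, 0 to 18 for the difference of effects, 3 to 7 for control EV and 0 to 1 for BDNF EV against control EV. The correlation of the change from control EV to BDNF EV with the BDNF change (0.0249) was 0.0662 over the 10510 genes of at least 10 CPM, 0.00742 to 0.0543 with 1 library left out and 0.0181 with the replicate block.

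Of the gene lists, an estimated correlation left 0 of 3 for EV against lysate in controls, 0 of 2 in BDNF cultures, 0 of 1 for EVs, 2 of 4 for lysates, 0 of 9 for hippocampal BDNF, 0 of 8 for control EV, 1 of 14 for BDNF EV and 0 of 11 between the EV groups. By fry on balance 1 way the counts were 6 and 5 for EV against lysate, 8 for lysates, 0 for control EV, 2 for BDNF EV and 0 between the EV groups. For hippocampal BDNF fry gave 8, of which 6 were among the 9 by camera. Cholesterol, oligodendrocyte and stress lists were lost, and microglial and glycolysis lists gained. By fry in either direction they were 9 and 9 for EV against lysate, 2 for EVs, 9 for lysates, 3 for the difference of effects, 16 for hippocampal BDNF, 0 for control EV, 6 for BDNF EV and 0 between the EV groups. The replicate block left the counts by camera as they were.

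Values that turned direction lay near 0 or differed between batches. For miR-132-3p in control EVs against lysates (0.00) they were −0.0848 with relative log expression, −0.0842 by DESeq2, −0.29 without the filter, −0.0850 at a minimum count of 50, −0.00208 with the replicate block, −0.00209 without the batch, −0.0655 without miR-9-5p, −0.0223 without the shallow EVs, −0.31 in batch z and −0.16 to 0.0358 with 1 library left out. For miR-218-5p in BDNF cultures (0.02) they were, for the same settings, −0.0457, −0.0459, −0.29 and −0.0645, then −0.14 without miR-9-5p, −0.0270 without the shallow EVs, −0.12 in batch z and −0.10 to 0.0420 with 1 library left out. miR-690 was at −0.0275 in batch x for EV against lysate in BDNF cultures and 0.33 in batch z in controls. In lysates after BDNF it was at 0.35 in batch z, 0.24 with the axis of spread and −0.24 to 0.0256 with 1 library left out. Neurod6 after BDNF was at 0.01003 in batch b, and miR-122-5p in lysates at 0.00732 with the axis.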

Other observations

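The genes of this part were chosen, as were the tests of them, after the BDNF results were seen. After EVs the mean levels of Npy, Nnat and Gal, among the genes that BDNF itself moved most, lay within 1 SD of the control mean. Npy stood at 8.16 ± 1.51 CPM after BDNF EVs and 7.50 ± 2.01 after control EVs (SD, n = 3 each), against 7.60 ± 1.71 in controls (SD, n = 6), and its log2 difference from the controls was 0.25 ± 0.13 (SE, edgeR adjusted p = 0.729) and 0.12 ± 0.14 (edgeR adjusted p = 0.940). Nnat stood at 997 ± 25.4 and 950 ± 98.6 CPM, against 1139 ± 204, and Gal at 0.216 ± 0.141 and 0.179 ± 0.0816 CPM (4.67 and 3.67 counts per library on average), against 0.202 ± 0.106.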
